A study of Mus musculus with 6 samples.

How the data were processed

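Poly(A) RNA sequencing was done on dendritic cells sorted by flow cytometry from the bone marrow of C57BL/6 mice, per the labels' protocols. The labels name 3 wild-type (WT) samples and 3 TCL samples, the latter from an adoptive transfer model of murine chronic lymphocytic leukaemia (CLL). The sort markers and the number of mice behind each sample are not given in the sources used here, so the p-values measure the spread between these samples, which may be partly technical.

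The submitters' processing notes name cutadapt, STAR 2.4.2a, HTSeq, DESeq2 and the mouse build mm10, without saying which step each served. The annotation and the strand setting of the counting are not given in the sources used here. The deposited table holds 24421 genes with a normalized signal for each of 6 libraries, per the file headers. Beside these values the authors deposited a mean over libraries, a log2 fold change, a p-value and an adjusted p-value per gene. These last columns are the authors' own comparison and are printed only as such. The columns are named by group and a running number, here WT libraries 3, 7 and 9 and TCL libraries 4, 8 and 10. These numbers do not follow the replicate numbers of the labels, so each column was used as a library of its group, without pairing.

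The normalized signal the authors deposited came from counts divided by a size factor. In each library 100% of the values above 0 were whole multiples of the smallest value, within a tolerance of 0.001 and with a largest deviation of 2.3e-09 from a whole number. Median-ratio factors recomputed from the recovered whole reads equalled the deposited ones. Recovered totals ran from 17158819 to 25674314 reads. Read totals hold only reads counted to the genes of the table.

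The comparison of TCL with WT was tested on the recovered reads with edgeR 4.0.16 (R 4.3.3), the test fixed before the data were examined for a table whose reads could be recovered. Genes were filtered with filterByExpr, which left 13010, and libraries were scaled with TMM factors. A quasi-likelihood test gave p-values, adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Standard errors were obtained as the absolute log2 fold change divided by the square root of F. Because the deposited values are normalized, a test on a log scale was added: limma 3.58.1 with a trend on log2 of the deposited value plus a pseudocount of 1 called 594 genes, against 604 with edgeR. Levels are CPM, reads scaled to the effective library size, as mean ± SD. Ratios of pooled reads of low genes have 95% intervals that cover counting error only. PCR reads are not independent molecules.

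In data simulated from the means and depths of these libraries, 3 against 3 over 12822 genes, edgeR recovered 55% of 2-fold and 97% of 4-fold changes. Of its 164 calls, 12 were false. A changed gene list was found in the simulation and 0 of 20 random lists were called. Genes were drawn independently there, so it does not show how often camera would falsely call lists of correlated genes. In these data the estimated correlation ran from -0.04 for the regulatory list to 0.94 for the erythroid list.

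Before the data were examined, 37 gene lists were fixed for dendritic cell subsets, other bone marrow cells and cell states. Of their 770 entries, 745 were found in the table, 2 of them through a synonym, and 719 were tested. The list of mitochondrially encoded mRNAs had no entry in the table used here, which left 36 lists. These were tested with camera of limma at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Camera compares a list with all other genes, and fry asks whether a list moves one way on balance. Counts of changed members are given over all genes tested and, separately, adjusted over the list alone. The mean log2 CPM of each list was also compared between groups with a two-sided exact permutation test, whose smallest possible p with 3 against 3 is 0.1. It took that value for 18 lists.

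Genes named in the text were chosen by a rule fixed before the data were examined. It took 10 genes whatever their result, up to 10 of the largest fold changes in each direction with a mean of at least 5 CPM and groups that do not overlap, and up to 4 members with the smallest adjusted p from each list. Predicted genes and receptor variable segments were left out of the second part. Other named genes are marked as chosen after their values were seen. Some genes the rule takes are not reported here. Gene positions are those of GENCODE on GRCm38, the assembly that mm10 stands for.

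Alternatives fixed in advance were other scaling factors, other filters, DESeq2 1.42.0, limma-voom, other thresholds, leaving out immunoglobulin genes, and leaving out each library. The limma-trend test, thinning to 1 depth, removal of the trend with GC content and transcript length, and counts per list without each library were added after the data were seen. So were 3 gene lists, of IL-10 and STAT3 responses, IL-4 and STAT6 responses, and complement and coagulation, which were written when the called genes were known. Genes of multigene families, such as Cd209a to Cd209d, Ly6i, Pira6, Apol11b and the class II genes, are uncertain where reads of near-identical copies could be divided or discarded.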

Results

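Gene expression was measured by poly(A) RNA sequencing in dendritic cells sorted from mouse bone marrow. Cells of 3 WT samples were set against cells of 3 TCL samples, taken from mice of an adoptive transfer model of CLL, in which leukaemic B cells are transplanted. The design asks how bone marrow dendritic cells differ when they share the marrow with this leukaemia. Recovered totals were 19291327, 17158819 and 22888203 reads in WT libraries 3, 7 and 9. They were 23392876, 22868112 and 25674314 reads in TCL libraries 4, 8 and 10. Of 24421 genes in the table, 16753 had a read and 13010 were tested.

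The TCL sorts carried more RNA of 10 of 21 tested interferon-gamma response genes. Of 22 inhibitory and regulatory genes 4 rose and 1 fell. The TCL sorts carried less RNA of 5 of 19 genes of the type 2 conventional dendritic cell list, 4 of them lectins. Genes of the neutrophil and macrophage lists were abundant too, S100a9 at 12489 CPM and Apoe at 5829 CPM in WT. No change can therefore be assigned to dendritic cells alone. Socs3, a feedback inhibitor of cytokine signalling, rose from 26.7 ± 9.54 CPM in WT to 274 ± 19.98 CPM in TCL (SD, n = 3 each). The gene lies at 117966079 to 117970047 of chromosome 11 (GRCm38). Cfb, which encodes complement factor B, rose from 21.0 ± 7.81 to 271 ± 58.8 CPM, and lies at 34856374 to 34862518 of chromosome 17. Mgl2, a C-type lectin that binds galactose-type sugars, fell from 216 ± 36.8 to 5.07 ± 0.730 CPM, and lies at 70130329 to 70137550 of chromosome 11. Of the stromal list 7 of 13 tested genes fell and 1 rose, and of the B cell list 9 of 22 fell, but 3 without WT library 7. Cxcl12, of the stromal list, had 137 ± 80.5 CPM in WT and 3.91 ± 2.78 CPM in TCL. None of these 5 lists was called by camera with an estimated correlation, nor the stromal and B cell lists by fry (adjusted p 0.066 and 0.111). Fry gave adjusted p-values of 0.0282, 0.00171 and 0.00511 for the interferon-gamma, regulatory and type 2 lists.

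In all, 604 genes changed in edgeR's quasi-likelihood test at an adjusted p under 0.05, 264 higher and 340 lower in TCL. Of these, 445 differed at least 2-fold, 171 higher and 274 lower. All 604 had groups that did not overlap. Among all tested genes 28.2% had such groups, where chance gives 10%. By the adjusted p of the authors' deposited table, 1359 genes passed, 654 higher and 705 lower, and all 604 were among them with the same direction. The count fell to 275 without WT library 3, 299 without WT library 7, 270 without WT library 9, 246 without TCL library 4 and 388 without TCL library 10. It was 904 without TCL library 8. With scaling to library size only, 54.3% of the calls were higher, against 43.7% with TMM factors.

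The first principal component held 71.8% of the variance of the 500 most variable genes and separated the groups. WT library 7 lay apart from the other WT libraries, at -50.2 on this component against -20.8 and -24.5. No libraries of a group differed by as little as sampling noise, with chi-square values per degree of freedom of 25.2 to 119.

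**Figure D1:**
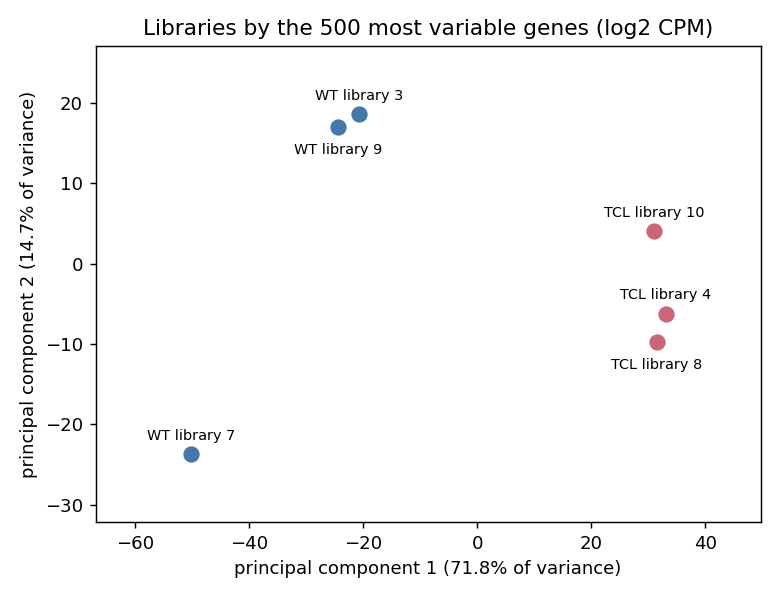
Principal components 1 (71.8% of variance) and 2 (14.7%) of log2 CPM over the 500 most variable genes, 1 dot per library, WT in blue and TCL in red. The 3 TCL libraries lie at 31.0 to 33.0 on component 1, and WT library 7 at -50.2, away from the other WT libraries.

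Of the genes set in advance, the integrin gene Itgax (CD11c), carried by most dendritic cells, had 475 ± 79.7 CPM in WT and 515 ± 140 CPM in TCL, a log2 fold change of 0.12 (SE 0.22, adjusted p 0.784). Its sign turned without WT library 7 (-0.014) and without TCL library 10 (-0.075). Zbtb46, a transcription factor of conventional dendritic cells, had a log2 fold change of 0.17 (SE 0.57, adjusted p 0.882), which turned without WT library 7 (-0.24) and TCL library 10 (-0.37). Flt3, the receptor for a growth factor of dendritic cells, fell by 1.19 on the log2 scale (SE 0.24, adjusted p 0.0271). It was not called without WT library 3 (adjusted p 0.0987), WT library 9 (0.066) or TCL library 4 (0.0937). Siglech, a marker of plasmacytoid cells, had a log2 fold change of 0.49 (SE 0.27, adjusted p 0.318). Cd84, a SLAM family receptor at position 171839697 to 171890718 of chromosome 1 (GRCm38), had 84.1 ± 3.39 CPM in WT and 67.5 ± 4.38 CPM in TCL. Its log2 fold change was -0.32 (SE 0.13, adjusted p 0.204), with groups that did not overlap, as in 28.2% of all tested genes. The mouse gene Tcl1 had 0 reads in every library, which does not show whether leukaemic cells were in the sorts. Ighm had no row in the table and is not analysed here.

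The genes with the largest rise were Apol11b, Gpr25, Cfb, Scarf2, Socs3, Ly6i, Ip6k3, Pira6, Spint1 and Irg1. Apol11b, of the apolipoprotein L family, had a log2 fold change of 4.89 (SE 0.91, adjusted p 0.0187) and was not called without WT library 7 or WT library 9. The orphan receptor gene Gpr25 had a log2 fold change of 4.65 (SE 0.67, adjusted p 0.00638), but was not called by limma-voom (adjusted p 0.106). Irg1, which makes itaconate, rose from 4.04 ± 0.742 to 33.3 ± 6.04 CPM, and the protease inhibitor gene Spint1 from 2.86 ± 0.244 to 26.0 ± 4.10 CPM. Scarf2 rested on unequal libraries, with 106 CPM in TCL library 8 and 10.6 and 19.8 CPM in TCL libraries 4 and 10. Its call and those of Ip6k3 and Pira6 were lost without WT library 3, and those of Scarf2 and Ip6k3 also without WT library 7. Scarf2 was not called without WT library 9 either. With no filter the calls of Apol11b, Scarf2, Ip6k3 and Pira6 were lost, and with limma-voom those of Apol11b, Scarf2 and Ip6k3, with adjusted p over all settings up to 0.13, 0.172, 0.0938 and 0.0847 in the order of the first list. Apol11b, Ly6i and Pira6 belong to families of close copies.

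The genes with the largest fall were Mmrn2, Cd209b, Ibsp, Adamts5, Mgl2, Abcc9, Cxcl12, Cd209c, Bgn and Col1a2. Mmrn2, an endothelial matrix gene, had 728 reads in WT and 6 in TCL, a ratio of 156 at equal depth (95% interval 71.3 to 426). The lectin gene Cd209b had 679 and 8 reads, a ratio of 109 (95% interval 55.0 to 254). Ibsp, Bgn and Col1a2 encode bone and connective tissue matrix proteins, and Col1a2 fell from 10.98 ± 9.43 to 0.375 ± 0.248 CPM. All 10 were called without any single library, but Ibsp (adjusted p 0.0546) and Col1a2 (0.0798) were not called by limma-voom.

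**Figure D2:**
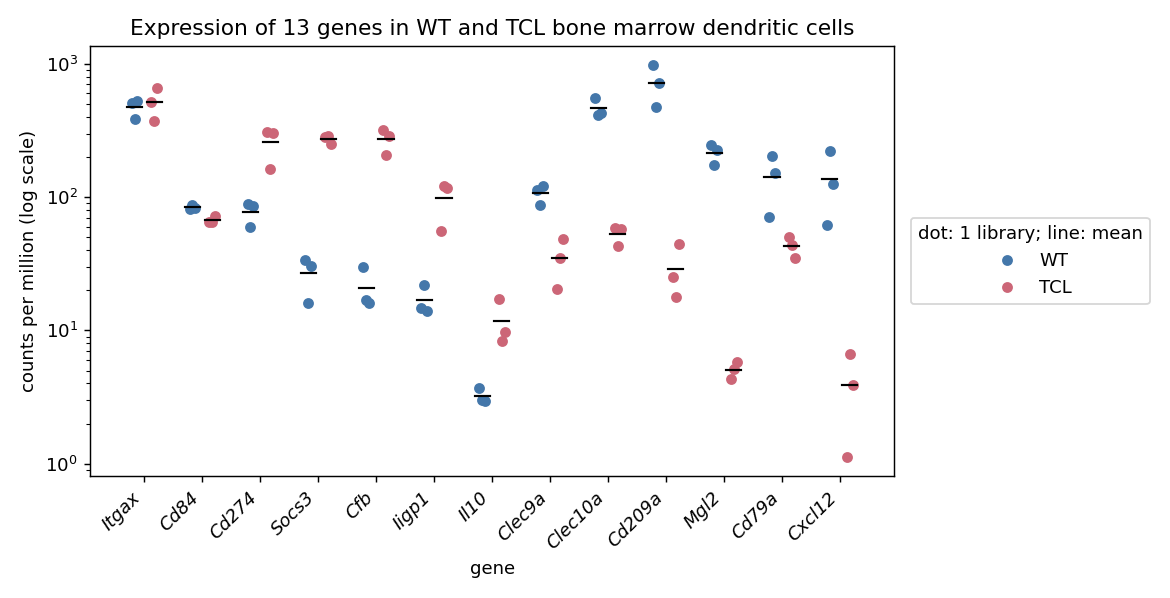
Counts scaled to library size (log axis) of 13 genes, with 1 dot per library (WT blue, TCL red) and the group mean as a line. Itgax overlaps between the groups. Cd84 is slightly lower in TCL without overlap, but was not called. Socs3 and Cfb are higher in TCL, and Mgl2 and Cxcl12 are lower in TCL.

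All 21 tested genes of the interferon-gamma response list were higher in TCL, with a median log2 fold change of 0.88. Of these 10 rose, 0 fell and 11 did not pass the test, and 16 rose when adjusted over the list alone. Iigp1, an interferon-inducible GTPase, rose from 16.8 ± 4.45 to 97.9 ± 36.7 CPM. The guanylate-binding protein genes Gbp7 and Gbp6 had log2 fold changes of 1.53 (SE 0.20) and 2.72 (SE 0.41). Cd274, which encodes the inhibitory ligand PD-L1, rose from 77.8 ± 16.2 to 259 ± 82.9 CPM (adjusted p 0.00759). The list was called by camera with an adjusted p of 1.19e-15, which was lost with an adjusted p of 0.182 with an estimated correlation. In the type I interferon list 6 of 32 genes rose, 0 fell and 26 did not pass, with 10 rising when adjusted over the list alone. Oas3, Oas2 and Zbp1 rose, with log2 fold changes of 0.90, 0.86 and 1.06. Camera gave an adjusted p of 5.21e-06, and of 0.411 with an estimated correlation. The count was 3 without WT library 7, 1 without WT library 9 and 2 without TCL library 4. Oas3, Oas2 and Zbp1 were each lost without at least 1 of these, with adjusted p up to 0.0634, 0.0582 and 0.067.

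Among inhibitory ligands and regulatory mediators 4 of 22 genes rose, 1 fell and 17 did not pass, and adjusted over the list alone 8 rose and 2 fell. Socs3, Cd274, Il10 and Il1rn rose. The anti-inflammatory cytokine gene Il10 went from 3.22 ± 0.400 to 11.8 ± 4.69 CPM, and Il1rn, which encodes an antagonist of interleukin 1, from 58.3 ± 8.31 to 148 ± 62.5 CPM. Il10 was not called without WT library 3, WT library 9 or TCL library 4 (adjusted p up to 0.0681), nor Il1rn without any library but TCL library 8 (up to 0.108). Camera gave an adjusted p of 0.00638, and of 0.182 with an estimated correlation. It was 0.0834 after the trend with GC content and length was removed. The number that rose was 2 without WT library 3, WT library 9 or TCL library 4, and the number that fell was 0 without any of those libraries, WT library 7 or TCL library 10, and 2 without TCL library 8.

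NF-kB pathway targets had 5 of 23 genes higher, 1 lower and 17 not passing, and adjusted over the list alone 9 rose and 2 fell. Bcl3, Tnfaip2, Sod2 and Tnip1 rose by 1.195, 1.21, 0.95 and 1.24 on the log2 scale. Cd83, a maturation marker, fell by 0.95. By camera the list had an adjusted p of 1.73e-05, and 0.399 with an estimated correlation. The number that rose was 10 without TCL library 8 and 3 without any other single library. The number that fell was 0 without WT library 3, WT library 9, TCL library 4 or TCL library 10. Of the glycolysis and hypoxia list 3 of 25 genes rose, namely Hif1a, Slc2a1 and Pdk1, 0 fell and 22 did not pass, with 8 rising when adjusted over the list alone. Its camera adjusted p was 6e-05, and 0.182 with an estimated correlation. The number was 0 without WT library 3, WT library 9 or TCL library 4, and 1 without TCL library 10. Of Toll-like receptors and their signalling genes 1 of 24 rose, Irak3, an inhibitor of this signalling, and 23 did not pass, with 7 rising and 1 falling when adjusted over the list alone. In camera its adjusted p was 0.0486, but 0.654 with an estimated correlation, 0.158 without WT library 7, 0.349 without TCL library 10, 0.114 with the filter of 5 CPM in 3 libraries and 0.116 after the GC and length trend was removed. The number that rose was 5 without TCL library 8 and 2 without TCL library 10, where 2 fell.

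Markers of type 2 conventional dendritic cells fell in 5 of 19 cases, 0 rose and 14 did not pass. Adjusted over the list alone 7 fell and 1 rose, and without TCL library 8 2 rose. The lectin genes Mgl2, Clec10a, Cd209a and Cd209d fell by 5.41, 3.13, 4.63 and 2.58 on the log2 scale (SE 0.21, 0.20, 0.40 and 0.37). Cd209a, at position 3743397 to 3748984 of chromosome 8 (GRCm38), went from 723 ± 249 to 29.1 ± 13.8 CPM. Sirpa, a surface marker of this subset chosen after its value was seen, had 1128 ± 25.2 CPM in WT and 1563 ± 290 CPM in TCL (adjusted p 0.159). Camera gave an adjusted p of 1.83e-10, and of 0.0663 with an estimated correlation. Of the type 1 list 3 of 18 genes fell, Cd36, Clec9a and Batf3, 0 rose and 15 did not pass, with 4 falling when adjusted over the list alone. Clec9a, a receptor for dead cells, fell by 1.62 (SE 0.28, adjusted p 0.0146), but had an adjusted p of 0.0573 without WT library 3. Camera returned an adjusted p of 1.26e-05, and 0.399 with an estimated correlation. The count was 1 without WT library 3 and 7 without TCL library 10.

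The general dendritic cell list had 1 of 17 genes higher, Traf1, and 3 lower, Batf3, Flt3 and Irf4, with 13 not passing. Adjusted over the list alone 1 rose and 5 fell. Its median log2 fold change was 0.09, but -0.17 without WT library 7, -0.22 without TCL library 10 and 0.21 without WT library 9, and its mean was -0.09. The camera adjusted p was 0.203, but 0.0272 without WT library 7 and 0.00651 without TCL library 10. Without WT library 3, WT library 9 or TCL library 4 no member was called, without WT library 7 1 fell, without TCL library 8 2 rose and 4 fell, and without TCL library 10 0 rose. Of plasmacytoid markers 1 of 21 rose, Lair1, and 20 did not pass, with 4 rising when adjusted over the list alone. Tested with camera, the list had an adjusted p of 0.0908, but 0.0105 without WT library 7, 0.0165 without TCL library 4 and 0.00455 without TCL library 10. Without TCL library 8 1 fell, and without TCL library 10 2 rose.

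Genes of MHC class II antigen presentation fell in 3 of 13 cases, H2-Ob, Lgmn and H2-DMa, 0 rose and 10 did not pass. Adjusted over the list alone 9 fell and 1 rose. H2-Aa, a chain of the class II molecule, had 11607 ± 1961 CPM in WT and 5870 ± 2327 CPM in TCL, a log2 fold change of -0.98 (SE 0.30, adjusted p 0.0993), and only DESeq2 among the settings called it. By camera the list had an adjusted p of 4.37e-05, and 0.399 with an estimated correlation. The count was 0 without WT library 3 or TCL library 4, 1 without WT library 7, WT library 9 or TCL library 10, and 5 without TCL library 8, where 1 rose. Of class I genes 0 of 17 passed in edgeR, 3 at an unadjusted p under 0.05 and 3 in DESeq2, while limma-voom and limma-trend called 0. Adjusted over the list alone 2 rose, and without TCL library 8 1 rose. The median log2 fold change was -0.01, from -0.065 without TCL library 8 to 0.12 without TCL library 10, and the mean 0.12, with camera upward at an adjusted p of 0.374. The maturation list had 1 of 19 genes higher, Il15ra, and 3 lower, the chemokine genes Ccl22 and Ccl17 and Cd83, with 15 not passing and the same numbers adjusted over the list alone. Its camera adjusted p was 0.179, but 0.0201 without WT library 7 and 0.00103 without TCL library 10. The number that fell was 1 without WT library 9, where Ccl17 had an adjusted p of 0.0685, and 3 rose without TCL library 8.

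**Figure D3:**
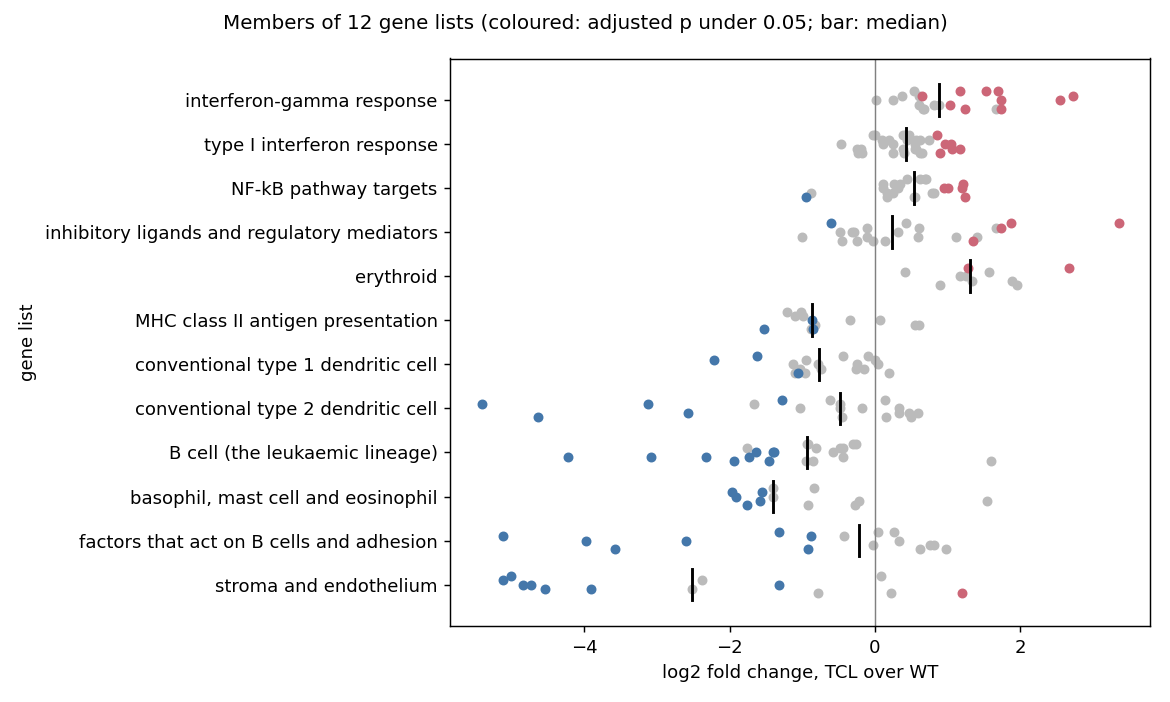
Log2 fold change, TCL over WT, of each tested member of 12 gene lists, 1 dot per gene, red or blue where it rose or fell at an adjusted p under 0.05, with the list median as a black bar. The 21 interferon-gamma genes all lie above 0, and the stromal list has its median at -2.52.

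Of 16 tested factors that act on B cells or adhesion 7 fell, 0 rose and 9 did not pass, and adjusted over the list alone 7 fell and 2 rose. Ccl22 fell by 3.98, the growth factor gene Igf1 by 2.60, Cxcl12 by 5.12 and the adhesion gene Vcam1 by 1.32 on the log2 scale. Cxcl12 and Vcam1 also belong to the stromal list. In camera its adjusted p was 2.37e-05, and 0.128 with an estimated correlation. The count was 4 without WT library 9, and 1 rose without TCL library 8. Of the C-type lectin, scavenger and Fc receptor list 3 of 23 genes rose, 6 fell and 14 did not pass, and adjusted over the list alone 4 rose and 9 fell. Mrc1, the mannose receptor gene, fell from 211 ± 23.5 to 26.0 ± 7.26 CPM, the haemoglobin scavenger receptor gene Cd163 fell by 3.02 and Cd36 by 2.21 on the log2 scale. Clec4e rose by 1.47. Camera returned an adjusted p of 0.000684, and 0.399 with an estimated correlation. It was 0.251 after the GC and length trend was removed.

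None of 11 SLAM family genes passed in edgeR (0 calls), where 4 had an unadjusted p under 0.05. DESeq2 called 2, and limma-voom and limma-trend 0. Ly9 had a log2 fold change of -0.79 (adjusted p 0.0793) and Slamf7 of -0.93 (adjusted p 0.144), beside Cd84 above. Tested with camera, the list had an adjusted p of 0.44, and 0 members were called adjusted over the list alone. Without TCL library 8 or TCL library 10 1 fell. Of inflammatory cytokines and chemokines 1 of 21 rose, Il1b, and 3 fell, Ccl9, Il18 and Cxcl16, with 17 not passing and 1 and 4 adjusted over the list alone. By camera the list had an adjusted p of 0.119, but was called downward with the filter of 5 CPM in 3 libraries (0.0385). No member rose without WT library 7, WT library 9 or TCL library 4, and 1 fell without WT library 3 or any of those.

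Of 22 tested B cell genes 9 fell, 0 rose and 13 did not pass, and adjusted over the list alone 15 fell and 1 rose. Fcer2a, Vpreb3, Tnfrsf13c and Cd79a fell by 4.22, 3.08, 1.46 and 1.73 on the log2 scale. In camera its adjusted p was 1.61e-10, and 0.333 with an estimated correlation. The count was 3 without WT library 7, WT library 9 or TCL library 10, and 4 without TCL library 4. Of the plasma cell list 2 of 11 fell, Jchain, the joining chain of immunoglobulins, which was not called with no filter (adjusted p 0.0741), from 1002 ± 380 to 83.5 ± 55.2 CPM, and Irf4, with 9 not passing and 5 falling when adjusted over the list alone. Irf4 also belongs to the general and the type 2 dendritic cell lists, where it is counted among the genes that fell. For the plasma cell list camera returned an adjusted p of 4.89e-05, and 0.128 with an estimated correlation. The count was 1 without any WT library or TCL library 4.

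Of 13 tested stromal and endothelial genes 7 fell, 1 rose and 5 did not pass, and adjusted over the list alone 9 fell and 1 rose. Sparc, a matrix protein gene, fell by 4.54 on the log2 scale, and Cxcl12, Vcam1 and Pecam1 had changes of -5.12, -1.32 and 1.203. Tested with camera, the list had an adjusted p of 2.58e-08, and 0.236 with an estimated correlation. The median log2 fold change of the list was -2.52, but -1.61 without WT library 7, -4.11 without TCL library 8 and -1.07 over the genes with at least 5 CPM in at least 3 libraries. The 7 genes that fell were all higher in WT library 7 than in the mean of the other WT libraries, as were all 9 called B cell genes, with median log2 ratios of 1.46 and 0.73. The 5 called type 2 genes had a ratio of -0.25. Of basophil, mast cell and eosinophil genes 5 of 12 fell, among them Prss34, Mcpt8, Cpa3 and Ms4a2, 0 rose and 7 did not pass, with 6 falling when adjusted over the list alone. By camera the list had an adjusted p of 0.000105, and 0.399 with an estimated correlation. The count was 0 without WT library 7, WT library 9, TCL library 4 or TCL library 10.

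Of 22 monocyte and macrophage genes 1 rose, Spic, named after its value was seen, 6 fell and 15 did not pass, and adjusted over the list alone 3 rose and 8 fell. Axl, Vcam1, Apoe and Adgre1 fell by 1.45, 1.32, 1.59 and 1.03 on the log2 scale, Apoe from 5829 ± 460 to 1932 ± 680 CPM. In camera its adjusted p was 0.00201, and 0.182 with an estimated correlation. It was 0.0991 after the GC and length trend was removed. The call of Adgre1 was lost without TCL library 4 (adjusted p 0.0575). The number that fell was 3 without TCL library 4 and 10 without TCL library 8. None rose without a WT library or TCL library 4, 3 rose without TCL library 8 and 2 without TCL library 10. Of 10 tested erythroid genes all were higher, with a median log2 fold change of 1.31 that was 0.70 without TCL library 8, 2 rose, Slc4a1 and Ermap, and 8 did not pass, with 8 rising when adjusted over the list alone. Ermap was lost without any WT library (adjusted p up to 0.13). Slc4a1, the red cell anion exchanger gene, went from 19.1 ± 1.601 to 122 ± 51.3 CPM. The globin genes Hba-a1, Hba-a2 and Hbb-bt had 0 reads and Hbb-bs 5 in WT and 20 in TCL, so they were not tested. Camera returned an adjusted p of 3.21e-07, and 0.399 with an estimated correlation. The count was 1 without any WT library and 5 without TCL library 10.

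Neutrophil transcripts were abundant in both groups, S100a9 at 12489 ± 4742 CPM in WT and 6372 ± 2746 CPM in TCL (adjusted p 0.175). The neutrophil list was also higher in WT library 7 than in the other WT libraries, with a median log2 ratio of 0.72. Of 16 tested genes 0 passed in edgeR, 4 had an unadjusted p under 0.05, DESeq2 called 2, and limma-voom, limma-trend and the adjustment over the list alone 0. Tested with camera, the list had an adjusted p of 0.0128, but 0.654 with an estimated correlation, 0.137 without WT library 7 and 0.242 without TCL library 10. The megakaryocyte list had 1 of 11 genes lower, Pf4, by 3.38 on the log2 scale, and 10 not passing, with 2 falling when adjusted over the list alone. By camera the list had an adjusted p of 0.00638, and 0.182 with an estimated correlation.

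The T cell list had 1 of 15 genes higher, Cd8a, and 14 not passing, with 2 rising and 3 falling when adjusted over the list alone. Its median was -0.02, but ran from -0.31 without TCL library 10 to 0.33 without WT library 7, its mean was 0.08 and its camera direction upward (adjusted p 0.771), and no gene was called without a WT library. The natural killer list had 1 of 14 genes higher, Gzmb, the granzyme B gene, by 2.46, and 2 lower, Klrd1 and Klrk1, with 11 not passing and 2 and 3 adjusted over the list alone. Its median was 0.10, but ran from -0.36 without TCL library 10 to 0.33 without TCL library 8, and its camera direction was downward (adjusted p 0.554, but 0.015 without TCL library 10). The number that fell was 1 without a WT library or TCL library 4, and 2 rose without TCL library 4. After the GC and length trend was removed 2 rose and 0 fell, with neither Klrd1 (adjusted p 0.0736) nor Klrk1 called. Of 14 progenitor genes 0 passed in edgeR, 3 had an unadjusted p under 0.05, DESeq2 called 2, and limma-voom and limma-trend 0. Adjusted over the list alone 2 fell, 2 fell without WT library 3, and the camera adjusted p was 0.289.

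Ribosomal protein genes fell in 2 of 39 cases, Rps24 and Rplp1, 0 rose and 37 did not pass, while 23 fell when adjusted over the list alone. The median log2 fold change was -0.60, with a camera adjusted p of 2.86e-09, and of 0.411 with an estimated correlation. After the GC and length trend was removed the median was -0.32, with a camera adjusted p of 8.07e-05 and 4 genes lower. The count was 4 without WT library 9 and 0 without any of WT library 3, WT library 7, TCL library 4 and TCL library 10. Ribosomal protein genes have many processed copies in the genome. Of 34 oxidative phosphorylation genes 0 passed in edgeR, 6 had an unadjusted p under 0.05, DESeq2 called 1, and limma-voom, limma-trend and the adjustment over the list alone 0. In camera its adjusted p was 0.0474, but 0.701 with an estimated correlation, 0.266 without WT library 3, 0.13 without WT library 7, 0.531 without TCL library 10 and 0.0712 with scaling to library size only. It was 0.66, in the other direction, after the GC and length trend was removed. Of 38 cell cycle genes 0 passed in edgeR and in DESeq2, limma-voom and limma-trend, and 0 adjusted over the list alone, with 3 at an unadjusted p under 0.05. Camera returned an adjusted p of 0.111, but 0.00923 without WT library 7, 0.00341 without TCL library 4 and 0.00223 without TCL library 10.

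Among the remaining lists, 1 of 21 unfolded protein response genes fell, Sdf2l1, with 2 falling when adjusted over the list alone. Its camera adjusted p was 0.00638, but 0.413 with an estimated correlation and 0.0534 without TCL library 10. The count was 0 without WT library 3 or TCL library 4 and 3 without TCL library 8. Of 19 cholesterol synthesis genes 1 rose and 1 fell, Cyp51, and 1 rose and 1 fell adjusted over the list alone, with 0 called without a WT library, TCL library 4 or TCL library 10 and 0 falling without TCL library 8 (camera adjusted p 0.418). Of 25 immediate early and heat shock genes Dusp1 and Hspa8 rose, with 2 rising and 1 falling adjusted over the list alone (camera adjusted p 0.51). None rose without WT library 7, WT library 9 or TCL library 4, 1 rose without WT library 3 or TCL library 10, 1 fell without TCL library 8 or TCL library 10. Of 20 apoptosis regulators Fas rose, and 2 rose adjusted over the list alone, with a camera adjusted p of 0.0725, which was 0.0399 with scaling to library size only, 0.0277 without TCL library 8 and 0.0332 after the GC and length trend was removed. Without TCL library 8 3 rose, and without any other single library 0 rose. Of 21 chemokine receptors and integrins S1pr1 and Ccr2 fell, and 5 rose and 4 fell adjusted over the list alone (camera adjusted p 0.418). Without WT library 9 or TCL library 4 0 fell, without WT library 3, WT library 7 or TCL library 10 1 fell, and 2 rose without TCL library 8.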

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

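The limma-trend test, the thinning and the GC and length correction were chosen after the data were seen. The numbers of changed genes with other scaling factors, filters, limma-voom, limma-trend, thinning, the GC and length correction and a 2-fold minimum lay within 1.5 times of 604, with 413 to 766 calls. DESeq2 called 1460, for a cause not tested. In the simulation it made 213 calls, 41 of them false, against 164 with 12 false for edgeR. It recovered 74% of 2-fold changes there, against 55% for edgeR. Thresholds of 0.01 and 0.1 gave 161 and 1240 genes, as their construction implies. Leaving out a library gave 246 to 904 genes, with fewer samples, and the cause of the rise without TCL library 8 was not tested. Camera called 22 of 36 lists, 21 to 24 without a library, but 0 with an estimated correlation, where 8 lists had an unadjusted p under 0.05 and the smallest adjusted p was 0.0663. Fry, which compares no list with other genes, called 8. They were the interferon-gamma, regulatory, glycolysis, type 2 dendritic cell, plasma cell, monocyte and megakaryocyte lists and the factors that act on B cells. The cause of these differences was not tested. Of 121 named genes tested, 104 passed, 48 of them under every setting, and 56 lost the call under at least 1. Apart from the calls lost without a library, limma-voom, another filter or scaling, or the GC and length correction ended more calls. These included Cd83, Lgmn, Cyp51, Dusp1, Mcpt8, Ms4a2, Prss34, Rplp1, Traf1, Cd8a, Ermap, H2-DMa, Il18, Il1rn, Pdk1 and C4b. The fold changes of Itgax and Zbtb46, not called, turned sign. Of called lists, the camera direction turned for oxidative phosphorylation, and the median turned for factors that act on B cells with no filter (0.054) and for the monocyte list after the GC and length correction (0.027). Without a library Itgax ran from -0.075 to 0.30 and Zbtb46 from -0.37 to 0.54, both negative without WT library 7 (-0.014 and -0.24) and TCL library 10. Among lists that turned, the adjusted p without a library ran from 0.00455 to 0.998 for plasmacytoid markers, 0.27 to 0.938 for T cells, 0.015 to 0.998 for natural killer cells, 0.00223 to 0.383 for the cell cycle and 0.211 to 0.78 for immediate early genes. In the turned direction it was 0.998, 0.625 and 0.723, 0.663 to 0.998, 0.353 and 0.485, in that order. After the GC and length correction natural killer cells (0.842) and oxidative phosphorylation (0.66) turned. The cause was not tested. Leaving out immunoglobulin genes removed 1 gene and says little. No paired analysis was possible because the column numbers do not follow the replicate numbers of the labels. The planned fits with a block were therefore not run. That reason covers pairing by the labels only. The columns also run in consecutive numbers, WT library 3 before TCL library 4, 7 before 8 and 9 before 10. A fit paired on these numbers was not run, and whether such libraries shared a batch was not tested. By mean log2 CPM, WT library 7 and TCL library 8 were each highest of their group for the neutrophil list. For the monocyte list they were lowest and highest. Depth limits the genes near 0 in TCL, whose fold changes depend on a few reads.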

Other observations

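The 3 gene lists of the next paragraph and their genes were chosen after the called genes were known. The tests of dendritic cell dilution and share, of the loss of 1 group of cells, of the IL-4 response, of carried-over cells and of a general loss of other cells were also chosen after the result was seen, as were the thinning and the GC and length correction. Some of these tests were revised after values had been seen. First versions of the tests of carried-over cells and of the IL-4 response counted genes already known to have changed and favoured those explanations, so both were replaced by tests on uncalled genes, whose medians lie nearer 0 by selection. The margin in the test of the loss of 1 group of cells was widened from 1 standard error to a 95% margin, without which that explanation would have been argued against. A limit was also added to the test of WT library 7, and the part of the share test over all tested type 2 members was added last, when its values were known.

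Of 23 tested genes known to respond to IL-10 and STAT3, 12 rose in TCL and 0 fell, with a median log2 fold change of 0.80. Il21r rose from 63.9 ± 12.1 to 167 ± 4.88 CPM, Nfil3 from 25.3 ± 2.42 to 57.4 ± 8.68 CPM, Pim1 from 75.4 ± 17.4 to 162 ± 11.5 CPM, and Stat3 itself from 246 ± 3.77 to 393 ± 37.9 CPM (SD, n = 3). Of 24 tested genes of the IL-4 and STAT6 response 11 fell, among them Ccl24, Mrc1 and Ccl22, and 1 rose, the receptor gene Il4ra, by 0.93 on the log2 scale, though 0 rose without WT library 7, WT library 9, TCL library 4 or TCL library 10 and 2 without TCL library 8. Adjusted over the 3 lists, camera gave p-values of 4.36e-10 and 9.49e-22, and of 0.00557 and 0.00281 with an estimated correlation. Of their tested genes 7 and 15 were also in lists fixed in advance. These lists were written when the called genes were known, so the p-values are not independent evidence. The uncalled members had medians of -0.01 and -0.33, with camera p-values of 0.447 and 0.316. The STAT3 count was 6 without WT library 3 or WT library 9 and 5 without TCL library 4, and that of IL-4 genes was 6 without WT library 9. Pim1 was lost without WT library 3 or TCL library 4 (adjusted p up to 0.0573), and Stat3 without any library but TCL library 8 (up to 0.105). Of 22 complement and coagulation genes 3 rose, Cfb, F10 and C4b, 3 fell, Serping1, C1s1 and C3ar1, and 16 did not pass, with a camera adjusted p of 0.377. C4b passed only narrowly (adjusted p 0.0485) and was lost without any library but WT library 7. It was also lost with limma-voom, upper quartile factors, the filter of 5 CPM in 3 libraries and the GC and length correction. Of this list 8 genes fell without TCL library 8, but 1 without WT library 7, WT library 9 or TCL library 10.

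The number of changed genes was 604 for the real grouping and 0 at most in the other splits of the 6 libraries, 3 against 3, where edgeR gave up to 1222 genes at an unadjusted p under 0.05. As many genes were called in 1 of the 10 splits, the real one, and 10 splits are too few for a share under 0.05. Every other split mixes WT and TCL libraries. A difference between the groups then widens the spread within each side, so few calls there would follow in any case.

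The interferon-gamma list was higher in TCL, where libraries were deeper on average, though not each one. After thinning every library to the smallest total its median log2 fold change was 0.87, against 0.88 before. Thinning leaves the expected ratio of scaled counts nearly unchanged, so it could not decide on depth. After removal of the GC and length trend the median was 0.75. This argues against GC content and transcript length as the whole source. If other cells had diluted the WT dendritic cells, Itgax and H2-Aa would be higher in TCL by about as much as the list. The upper 95% limits of their log2 fold changes were 0.61 and -0.30. The limit of their mean, -0.012, treats them as independent and lies under 0 through H2-Aa. That gene is of the class II list, where 3 of 13 genes fell and 0 rose. These values argue against dilution only if Itgax was not a sort marker and H2-Aa did not change within the cells. A response of the dendritic cells to the leukaemia, or a shift between dendritic cell subsets, may account for the list, and neither was tested.

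Lectin genes of the type 2 list fell. A lower share of dendritic cells in the TCL sorts would lower Itgax alike, unless the sort selected for it. The lower 95% limit of its log2 fold change was -0.38, above the median of the 5 called members (-3.13). The sort markers are not given, so this does not decide whether the share was lower. All 19 tested members had a median of -0.48 with 7 higher, which Itgax also leaves open. Of other genes set in advance, Flt3 fell by 1.19 on the log2 scale and Zbtb46 had a change of 0.17. The loss of 1 group of cells stays open: 36.8% of the tested members were lower by at least 1 on the log2 scale, and their median is too uncertain to exclude it. A weaker IL-4 response may also account for it, but the uncalled genes of that list outside the type 2 list had a median of -0.33 (camera p 0.316, and 0.351 with an estimated correlation), which leaves it open. All the listed genes outside the type 2 list had a median of -0.99, a value the choice of genes may have set, and the leukaemia as a reason was not tested.

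Of 13 tested stromal genes 7 fell in TCL and 1 rose, of 22 tested B cell genes 9 fell and 0 rose, and those that fell were higher in WT library 7 than in the mean of the other WT libraries. That library alone does not account for the medians, which without it were -0.82 for B cell and -1.61 for stromal genes. Their upper 95% limits, -0.26 and -0.30, treat the genes as independent and do not measure the spread between libraries. Without that library 3 B cell and 5 stromal genes were still called lower. The tested erythroid genes argue against a general loss of all other cells from the TCL sorts. Their median log2 fold change was 1.31, and 0.70 without TCL library 8, where 9 of 10 were still higher. Only 2 of them were called, and the estimated correlation of the list was 0.94, so these genes are not independent. The globin genes of the list were not tested. Carried-over cells in varying amounts remain a candidate explanation: uncalled members also had medians of -0.57 and -0.79, but their ratios in WT library 7 were 0.36 and -0.16, so the test left it open. The leukaemia as a reason for fewer stromal and B cell transcripts was not tested.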
